A study of Salmo salar with 60 samples.

How the data were processed

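Total RNA from the distal intestine of single Atlantic salmon was labelled with Cy5 and hybridised to 2-colour oligonucleotide arrays together with a Cy3-labelled pool of 18 fish, per the labels' protocols. No dyes were swapped, so a dye effect common to all arrays cancels between days. Each fish had 1 array, and the replicates of a day are separate fish, per the labels. Days and tanks were taken from the sample titles. The array labelled day 1 and tank 0 was left out of the group comparisons because the design has tanks 1 and 2 only, and because with it the titles would give 11 fish of day 1 and 9 of day 0.

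For each array the authors deposited scanner intensity values in both channels, given as the median signal of each spot after background correction, per the file headers. The method of correction and the scanner software are not given in the sources used here. Each file held 45220 spots, of which 1531 control spots were absent from the series' value table. Flag codes were deposited without a key. Code 1 covered the controls and 62 further probes on some array, which were left out; code 2 fell on 6.13% of probe values, with a median Cy5 signal of 12.5, and code 3 on 1.95%, with a median of 40593. Codes 2 and 3 were kept. The authors also deposited a table of log2 values for the same arrays. Against the scanner values, over 14678 probes above 100 in both channels on all arrays, its columns behaved as log2(Cy5/Cy3) centred on each probe's median over the 60 arrays. Each of the 60 columns correlated best with its own array, at 0.949 to 0.997, and at most 0.836 with another array. Column medians ran from -0.0233 to 0.0254. Which within-array normalization the authors used is not given in the sources used here.

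The corrected signals were used without a further background model. Values below 0, 1.94% of Cy5 and 1.15% of Cy3 values, were set to 0, and 50 was added to both channels. This offset shrinks the ratio of dim probes, so their changes are understated, for 43.8% of probes to the point that loss of all signal would stay below 2-fold. Log2(Cy5/Cy3) was then normalized within each array by loess. Before the data were examined, normexp with an offset of 50 had been planned unless the values were already corrected, which they were. Log ratios of 2 arrays correlated from -0.447 to 0.625 over all probes. The direction of the ratio rests on the labels, which state the dyes. The positive match of every value table column to its own array cannot check it, because both hold the same 2 channels.

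Day means were fitted to 59 arrays with lmFit and eBayes in limma 3.58.1 under R 4.3.3, without covariates, and p-values were adjusted by the Benjamini-Hochberg method over 43627 probes. The contrasts were each feeding day against day 0 and each day against the one before. A second model with day, tank and their interaction gave the test of a difference between tanks. The p-values measure the spread between fish and do not include a tank effect, as there were 2 tanks. Principal components were computed on the log ratios, and single values were tested by exact enumeration of splits or by 100000 permutations. The shared day 0 fish had been meant to be split into 2 sets, and were split into 3 because 3 days were compared.

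The fit was tested on simulated data made from label-shuffled residuals of these arrays. With 200 of 43627 probes changed at day 7 against day 0, it recovered 36.0% of changes of 0.5 on the log2 scale, 91.5% of changes of 1, 97.5% of 1.5 and 99.8% of 2, averaged over 20 draws. All sizes were mixed in each draw, with the 200 probes divided among them. The larger changes eased the adjusted threshold for the smaller ones, which would be recovered less often alone. These sizes are on the offset scale, where a dim probe needs a larger change in RNA, or cannot reach them. It made 14.8 false calls per draw on average, and 1 of 20 draws without any change gave calls. The test of tanks recovered 94.4% of 200 probes changed by 2 log2 units in one tank on day 7.

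Alternatives fixed before the data were examined covered background, normalization, the authors' table, dim probes, slide, position, tank, replicate number, spread estimate, array weights, threshold, single tanks and the array labelled tank 0. Others were added after seeing the data. Gene lists had been fixed beforehand, but the files name probes by position and the gene table used here could not be joined to them, so gene lists, and the rule for named genes (the 10 largest changes in each direction among probes past the threshold), gave no result. The 4 probes named instead were chosen after their values were seen, by the smallest p on day 3 among probes above the lowest 25% of mean intensity with the same sign in both tanks.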

Results

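Gene expression was profiled in hindgut tissue (distal intestine) of Atlantic salmon during the first week on a diet with soybean meal, a plant protein source that causes inflammation of this part of the gut in salmonids. Fish were adapted to a fishmeal diet, which held 563 g of fishmeal per kg, and sampled on day 0. The remaining fish, in 2 tanks, then received a diet with 200 g of soybean meal per kg and were sampled after 1, 2, 3, 5 and 7 days. RNA of each fish was labelled with Cy5 and hybridised with a common Cy3 reference pool of 18 fish, 3 of each sampling day. The 60 arrays comprised 9 fish labelled day 0 with a tank of the design, 10 fish each of days 1, 2, 3, 5 and 7, and 1 array labelled day 1 and tank 0 that entered no comparison between groups. The arrays lay on 15 slides of 4. The median background-corrected Cy5 signal was 76.5 ± 14.9 (SD, n = 59) and the median Cy3 signal was 73.7 ± 9.76. By day, the Cy5 value ran from 65.2 ± 5.56 on day 1 to 83.4 ± 19.9 on day 3 (n = 10 each). The Cy3 value ran from 70.6 on day 7 to 77.1 on day 3. After exclusion of controls and flagged probes, 43627 probes were tested. Probes carried only a position on the array, so genes and gene groups are not analysed here. The number of arrays limits the precision of every value.

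The comparison of each feeding day with day 0 asked which transcripts had changed by then. With limma, 0 probes passed a Benjamini-Hochberg adjusted p of 0.05 on any of the 5 feeding days. The smallest adjusted p was 0.956 on day 3 and 0.989 on day 5. At an unadjusted p under 0.05, limma counted 1230 probes on day 1, of which 624 were higher and 606 lower than on day 0. It counted 1309 probes on day 2, with 690 higher and 619 lower. On day 3 there were 2085 probes, 1167 higher and 918 lower. On day 5 there were 1756, with 941 higher and 815 lower (3926 in all with array quality weights), and on day 7 there were 1260, with 670 higher and 590 lower. For 43627 probes without any change, 2181 would be counted on average at this threshold. An exact Wilcoxon rank sum test per probe called 0 probes on each day after adjustment. With 92378 possible splits of the fish, its smallest p is too large for a few probes to pass, however well separated. Its count of 0 therefore adds little to that of limma. At an unadjusted p under 0.05 it gave 1194, 1363, 2032, 1531 and 1219 probes on days 1, 2, 3, 5 and 7. The p-values treat the fish as independent, although those of a day came from only 2 tanks. Every comparison rests on the deposited day labels, which no measured value here checks.

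**Figure D1:**
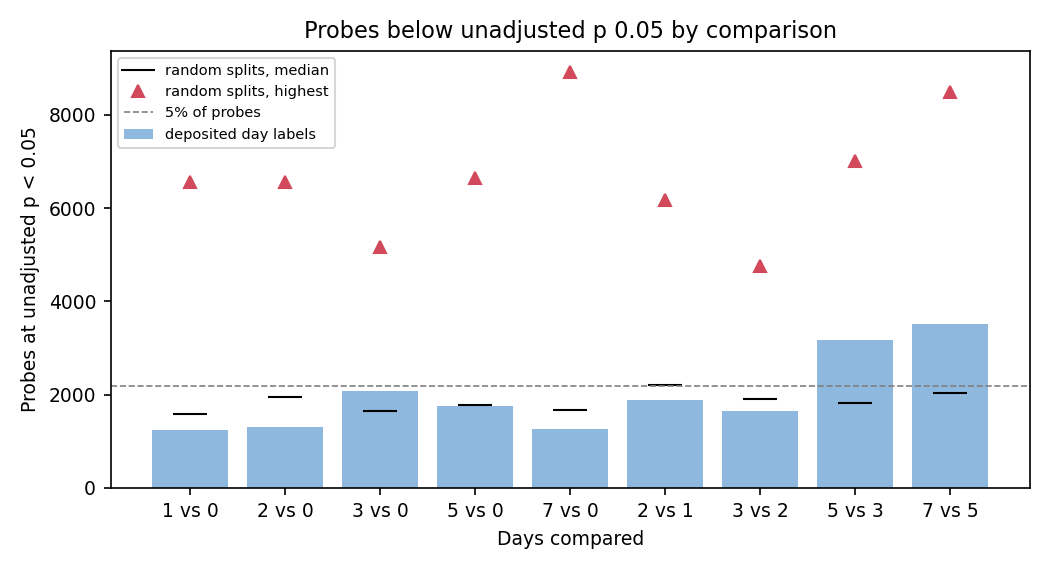
Number of probes at an unadjusted p under 0.05 (vertical axis) in each of the 9 comparisons of days (horizontal axis). Bars show the deposited day labels, black dashes the median and red triangles the highest of 99 random splits of the same arrays, and the dashed line the 2181 probes equal to 5% of those tested; the bars for day 5 against day 3 (3165) and day 7 against day 5 (3508) lie above that line and below the triangles.

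The size of change that the arrays could exclude depended on signal. For 19117 probes, 43.8% of those tested, the offset of 50 means that loss of all signal would move the ratio by less than 2-fold, so an interval within 2-fold bounds no decrease there. Of the 16234 probes whose mean intensity over both channels equals a signal above 200, chosen as bright after seeing the data, the 95% confidence interval of the change from day 0 lay within 2-fold in either direction for 96.0% on day 1, 96.0% on day 2, 94.2% on day 3, 93.5% on day 5 and 95.6% on day 7. Without the offset, these shares were 94.0%, 94.0%, 92.2%, 91.0% and 93.9%. Over all probes without the offset, they were only 55.6%, 55.7%, 54.8%, 54.2% and 55.6%. The median half-width of the interval for bright probes was 0.33 on the log2 scale with the offset and 0.365 without it. The estimate itself exceeded 2-fold, on the offset scale and over all probes, for 23 probes on day 1, 8 on day 2, 33 on day 3, 49 on day 5 and 5 on day 7. On the offset scale, the standard deviation between fish of a day was 0.31 for the median probe, 0.51 at the 90th percentile and 1 at the 99th percentile, in log2 units.

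Since no probe passed the test, 4 probes were chosen after their values were seen, as those with the smallest unadjusted p on day 3 in each direction among brighter probes with the same sign in both tanks. Probe C036R023 had a log2 ratio to the reference pool of -0.33 ± 0.45 (SD, n = 9) on day 0 and 0.67 ± 0.45 (n = 10) on day 3. The difference of 1.00 had a standard error of 0.23. Its differences from day 0 were 0.49 on day 1, 0.74 on day 2, 0.12 on day 5 and 0.34 on day 7. Probe C182R153 was at -0.33 ± 0.28 on day 0 and 0.52 ± 0.34 on day 3, a difference of 0.85 with a standard error of 0.20. Its differences were 0.06 on day 1, 0.36 on day 2, 0.68 on day 5 and 0.32 on day 7. Probe C016R082 was at 0.20 ± 0.54 on day 0 and -0.54 ± 0.32 on day 3, a difference of -0.74 with a standard error of 0.17. Its differences were -0.08 on day 1, -0.31 on day 2, 0.13 on day 5 and -0.16 on day 7. Probe C225R089 was at 0.39 ± 0.34 on day 0 and -0.20 ± 0.28 on day 3, a difference of -0.59 with a standard error of 0.15. Its differences were -0.27 on day 1, -0.38 on day 2, -0.39 on day 5 and -0.25 on day 7. The other days share with day 3 the day 0 fish, whose values entered the choice, so they add no separate support. Probes C016R082 and C225R089 were dimmer than the bright probes defined above. Without the offset their day 3 differences were -1.06 and -0.87. The limma adjusted p on day 3 was 0.956 for each of the 4 probes, and 10 of 10 fish of day 3 lay on the stated side of the day 0 mean for each. Probes chosen for a small p stand apart in this way even without an effect.

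**Figure D2:**
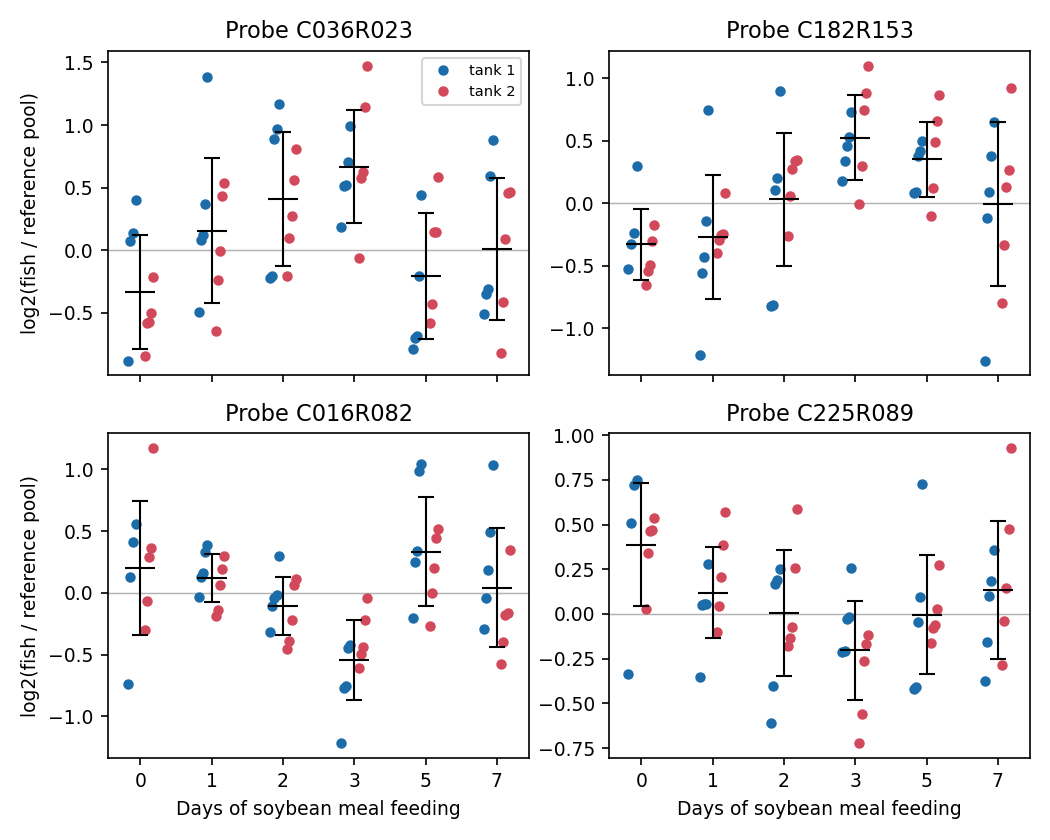
Log2 ratio of fish over reference pool (vertical axes) for 4 probes by days of soybean meal feeding (horizontal axes). Points are single fish, blue for tank 1 and red for tank 2, and black bars show the mean ± SD of each day (n = 9 on day 0, n = 10 on the others); the day 3 means of 0.67, 0.52, -0.54 and -0.20 stand against day 0 means of -0.33, -0.33, 0.20 and 0.39.

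Successive sampling days were compared to ask when expression moved, without the shared day 0 fish. Neighbouring comparisons still share a day. Day 5 against day 3 and day 7 against day 5 both use the day 5 fish, so their counts are not independent. With limma, 0 probes passed the adjusted threshold in each of the 4 comparisons of successive days. The smallest adjusted p was 0.666 for day 2 against day 1, 0.956 for day 3 against day 2, 0.0764 for day 5 against day 3 and 0.0829 for day 7 against day 5. At an unadjusted p under 0.05 there were 1884 probes for day 2 against day 1 and 1645 for day 3 against day 2. With median centring in place of loess, day 2 against day 1 had 3625. There were 3165 probes for day 5 against day 3, of which 1496 were higher and 1669 lower on day 5. There were 3508 for day 7 against day 5, of which 1688 were higher and 1820 lower on day 7. The exact Wilcoxon test called 0 probes in the same 4 comparisons after adjustment, where 184756 possible splits again leave little room for calls. It counted 1621, 1400, 3136 and 2926 at an unadjusted p under 0.05. With array quality weights in the fit, limma called 802 probes for day 7 against day 5 and 1 for day 5 against day 3. The unadjusted count for day 7 against day 5 was then 7227. Replicates 2 and 7 of day 7 had low weights, 0.433 and 0.381. Leaving out the one or the other without weights gave 5128 and 5125 probes at an unadjusted p under 0.05. Calls under further settings are given below. A test for any difference among the 6 days called 0 probes with limma, with 2129 at an unadjusted p under 0.05 and a smallest adjusted p of 0.924.

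The share of the variation in all probes that lay between the days was 8.33%, against a mean of 8.62% when day labels were shuffled over the 59 arrays (permutation p = 0.523, adjusted p = 0.548 over 4 labels). Slides held 26.6%, against 24.1% for shuffled labels (permutation p = 0.127). Tanks held 1.86% (permutation p = 0.268) and positions on the slide 4.83% (permutation p = 0.548). Of the 9 pairs of days, day 5 against day 3 had the lowest exact permutation p, with 7.32% of the variation between the days and p = 0.0768 over 184756 splits (adjusted p = 0.691). For day 7 against day 0 the share was 3.44% (exact permutation p = 0.927).

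The first principal component of the 59 arrays held 26.9% of the variation. Its scores averaged 0.365 ± 48.0 (SD, n = 9) on day 0, 7.19 ± 38.6 on day 1, 3.04 ± 47.6 on day 2, 0.878 ± 20.7 on day 3, -20.3 ± 41.2 on day 5 and 8.88 ± 53.8 on day 7 (n = 10 each). Days accounted for 5.38% of the variation in these scores (permutation p = 0.701). The second component held 5.77% of the variation and averaged -2.35 ± 11.1 on day 0 (n = 9), -11.2 ± 18.1 on day 1, 5.29 ± 17.6 on day 2, 16.6 ± 17.1 on day 3, -1.88 ± 20.0 on day 5 and -6.75 ± 21.8 on day 7. Days accounted for 21.9% of its scores, with a permutation p of 0.019 that became 0.228 after adjustment over the 12 tests of 3 components and 4 labels.

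**Figure D3:**
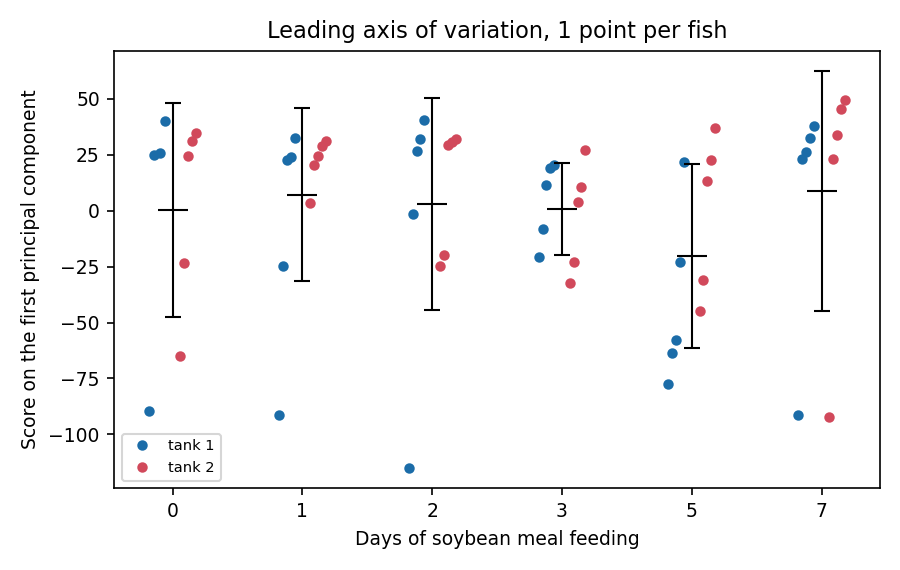
Score on the first principal component of the log ratios (vertical axis, a weighted sum of log2 ratios without a unit of its own) by days of soybean meal feeding (horizontal axis). Points are single fish, blue for tank 1 and red for tank 2, and black bars show the mean ± SD of each day; scores reach -89.4 on day 0, -115 on day 2 and -92.3 on day 7, and the lowest on day 3 is -32.4.

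The fish of each day came from 2 tanks, and the design allowed a test of whether the change differed between them. With limma, 0 probes passed the F test of the day by tank terms after adjustment, with a smallest adjusted p of 0.594 and 1666 probes at an unadjusted p under 0.05. The changes from day 0, taken in each tank against its own day 0 fish, correlated across probes at -0.12 on day 1, -0.10 on day 2, 0.16 on day 3, -0.02 on day 5 and 0.04 on day 7. Probes are not independent replicates, so each correlation was set against all 31752 splits of the fish within tanks, and the lowest two-sided exact permutation p was 0.346, on day 3. The share of probes with the same sign in both tanks was 47.2%, 47.6%, 54.6%, 49.7% and 51.3% on days 1, 2, 3, 5 and 7.

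Persistence was taken as a change in one direction on each of days 3, 5 and 7. After adjustment limma gave 0 such probes, and 78 had an unadjusted p under 0.05 on all of these days in one direction. Since the days share the day 0 fish, days 1 to 7 were simulated around each probe's mean over all arrays compared, against the real day 0 arrays. The 20 simulated sets gave 41 to 85 probes with a mean of 58.1, a range that holds the observed 78, while independent lists would share 0.618. That mean includes the fed fish, so a lasting difference from day 0 would remain in the simulated sets. Noise was also drawn separately for each probe. The range therefore cannot tell a lasting change from the effect of shared day 0 fish. With the day 0 fish divided into 3 sets of 3 and each day set against its own set, 0 probes had an unadjusted p under 0.05 on each of the 3 days in one direction; with so few day 0 fish in a set and 0.618 probes expected of independent lists, this count says nothing on the source of the 78.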

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

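All tests in this part were chosen after the results were seen. Within days, 48 sets of values (4 properties of the arrays and 4 probes on 6 days) were searched for a fish far from the others, and 4 were found where chance gives about 2.4. On the first principal component, replicate 7 of day 1 scored -91.3, with the next fish of that day at -24.5. Replicate 10 of day 2 scored -115, with the next at -24.8. The search was for single fish and misses pairs. On the same component, replicates 2 and 7 of day 7 scored -92.3 and -91.2, with the next fish of that day at 23.1. Replicates 7 and 2 of day 0 scored -89.4 and -65, with the next at -23.4. The median Cy5 signal of replicate 4 of day 7 was 55.5, below the next lowest of 71. Probe C182R153 had a log2 ratio of 0.298 in replicate 9 of day 0, above the next highest of -0.172.

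The first component held 26.9% of the variation while days accounted for 5.38% of its scores, and low scores occurred on day 0 (down to -89.4) as well as after feeding. A slide effect as its whole source is argued against by the 68.8% of the variation in scores that lay within slides. A response of each fish to soybean meal would need similar day 0 fish, but their SD was 1.16 times that of fed fish (95% interval 0.739 to 2.26), if the day labels are right. This interval assumes normal scores, and with 9 day 0 fish and outlying low scores it is only approximate. Scores ran from -89.4 to 40.1 in day 0 fish and from -115 to 49.7 in fed fish. The score correlated with the log2 ratio of the median Cy5 and Cy3 signals over 59 arrays (r = -0.579, permutation p = 1e-05, the smallest that 100000 permutations can give; rho = -0.503, permutation p = 6e-05; adjusted p = 3e-05 over 3 relations; -0.577 without the 2 farthest arrays; -0.548 within slides), so uneven labelling may contribute, but a real shift in abundant transcripts could move that ratio too and the 2 cannot be told apart. Exchanged labels stay open as well: a day 0 fish ranked 5 of 59 by distance from the median score, which exchanged labels and differences between fish unrelated to the diet would both give; were labels exchanged, the counts of 0 and the bounds on change would not describe the feeding days.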

How the results depend on the processing

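The added settings (a floor of 1 without offset, the Wilcoxon test, probes with mean intensity above 8, component covariates and single arrays left out) were chosen after the results were seen. Under each setting run, limma called 0 probes for days 1, 2 and 7 against day 0 and for day 3 against day 2. The tank test and persistence also gave 0 under each setting run for them. The Wilcoxon test called 0 in the day comparisons, where its smallest possible p left little room for calls. Counts at an unadjusted p under 0.05 ran from 145 to 2245, 205 to 2259, 745 to 3991, 577 to 4479 and 176 to 2351 on days 1, 2, 3, 5 and 7 against day 0, up to 3625, 2976, 6363 and 7227 for successive days, and from 451 to 2136 for the tank test and 1 to 121 for persistence. The lowest were those with intensity above 8. The authors' table, median centring, normexp, slide, position, either assignment of the array labelled tank 0 and either tank alone gave 0 in every comparison run. Quantile scaling leaves log ratios unchanged. The 4 named probes kept their sign wherever run (not with the Wilcoxon test or left-out arrays). Selection fixed it in single tanks, and other settings reuse the selected values. An adjusted p under 0.05 came only with 3 residual components (0.00725 to 0.0294).

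Counts for day 5 against day 3 and day 7 against day 5 were 2 and 1 with an intensity trend and robust moderation. They were 1 and 802 with array weights, and 1 and 1 for probes with mean intensity above 8. With tank within day as a random block they were 2 and 3, but a block correlation of -0.028 narrows errors. The replicate block gave 1 for day 7 against day 5 and 0 elsewhere. Same-numbered fish of different days are separate fish, nearly all from the same tank. Their deviations correlated at 0.0297 on average (-0.528 to 0.689). With 1 residual component the counts were 81 for day 5 against day 0, 758 for day 5 against day 3 and 1500 for day 7 against day 5. With 3 they were 101 for day 3 and 359 for day 5 against day 0, 13 for day 2 against day 1, 1580 for day 5 against day 3 and 2263 for day 7 against day 5. Residual components shrink the error without adjusting the day means; the first component of the arrays, which adjusts both, gave 0 in all 9 comparisons. The cause of the other shifts was not tested.

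Leaving out 1 array at a time gave 0 to 2 probes for day 5 against day 3 (1 without replicate 6 of day 0, replicate 1 of day 3, or replicate 1 or 5 of day 5; 2 without replicate 4 of day 5 or replicate 7 of day 7) and 0 to 5 for day 7 against day 5 (5 without replicate 2 of day 5; 2 without replicate 1 of day 7; 1 without replicate 1 of day 0, replicate 7 of day 3 or replicate 10 of day 5). It gave 0 to 0 in the others. Gene list settings were not run, and the offset hides small and large changes of dim probes.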

Other observations

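The tests in this part were chosen after the results were seen. Random splits of the arrays of 2 days, 100 per comparison with the real one included, decide nothing for the 11 counts of 0, since all 100 splits give at least 0 whatever the data. The highest count in another split was 1 for each of days 1, 2, 3 and 5 against day 0, 1996 for day 7 against day 0, 9 for day 2 against day 1, 48 for day 3 against day 2, 6 for day 5 against day 3, 1494 for day 7 against day 5, 6 for the tank test and 0 for persistence. The splits with 1996 and 1494 probes were those of the 99 others that parted their 2 groups most on the first component, by 61.2 and 56.0 in mean score, against 8.51 and 29.2 for the real days 7 and 0 and 7 and 5. The component was computed from the same log ratios, so calls in splits along it are no independent support for its meaning. A wide gap did not always bring many calls. The widest splits for day 3 against day 0 and day 5 against day 3, with gaps of 40.4 and 42.5, gave 1 and 6 probes. The split with 48 probes for day 3 against day 2 had a gap of 15.8, the rank 46 among its 99, so that this count did not follow the component.

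At an unadjusted p under 0.05, as many probes as observed were found in 93, 90, 17, 52 and 95 of 100 splits for days 1, 2, 3, 5 and 7 against day 0 (highest other 6559, 6560, 5167, 6653 and 8927). The number of splits was 64 for day 2 against day 1, 82 for day 3 against day 2, 12 for day 5 against day 3 and 13 for day 7 against day 5 (highest other 6181, 4753, 7015 and 8479). It was 68 for the tank test (highest other 5492) and 89 for persistence (highest other 675). Chance was therefore not excluded for any of these counts.

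Of the higher counts under other settings, only those named in this paragraph were set against splits in the same way. The counts with 1 residual component, among others, were not. With 3 residual components as covariates, 11 of 100 splits reached the 1580 probes of day 5 against day 3 (highest other 5877) and 26 reached the 2263 of day 7 against day 5 (highest other 7988), so chance was not excluded. Of the 99 other splits of day 7 against day 5, 77 gave at least 1 probe with these covariates. With array weights, 2 of 100 splits reached the 802 probes of day 7 against day 5, the real one included (highest other 938). Such a count was thus uncommon among the splits, although another split exceeded it. Chance was not excluded for a count picked from 9 comparisons and all settings run.

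Probes with a mean intensity A above 8 were 36.9% of those tested. Of the probes at an unadjusted p under 0.05 they made up 12.1%, 16% and 14.4% on days 1, 2 and 7 against day 0, so that these counts lay mostly in dimmer probes. They made up 36.5% on day 3 and 33.9% on day 5 against day 0, and 28.9% and 22% for day 2 against day 1 and day 3 against day 2. For day 5 against day 3 they made up 50%, and for day 7 against day 5 57.3%, more than their share of the probes tested.

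The array labelled day 1 and tank 0 had a median Cy5 signal of 85 and a median Cy3 signal of 77. Its score on the first component was 25.0 and on the second 6.81, both inside the ranges of day 0 (-89.4 to 40.1 and -15.5 to 15) and of day 1 (-91.3 to 32.4 and -38.1 to 13).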
